A study of Mus musculus with 22 samples.

How the data were processed

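The series holds 22 mouse samples, of which 8 are RNA-seq libraries in 4 groups of 2 and 14 are ATAC-seq samples that were not analysed here. Per the labels' protocols, small numbers of sorted cells were made into strand-specific libraries and sequenced as read pairs. The deposited values are FPKM, fragments per kilobase of gene scaled to the mapped fragments of a library, 1 value per gene name and library, per the file headers. The submitters' processing notes name Trim Galore 0.6.7, HISAT2 2.2.1, SAMtools 1.15, StringTie 3.0.1, MACS2 2.2.7.1 and HOMER 4.11 and the genome build mm10, without saying which tool served which assay. All RNA samples are labelled as lung, although the design text describes circulating cells taken from blood. The annotation, the strand setting and any filter are not given in the sources used here.

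Groups and replicate numbers were taken from the sample titles. Values of one gene name were summed where a name occurred more than once, which gave 55291 names per library, of which 53292 (96.4%) matched the gene table used. FPKM values summed to 323363 in circulating ex-TRM replicate 1 and to 939087 to 1632198 in the other libraries, and protein-coding names held 10.2% to 28.1% of these sums. No library held values identical to those of another. Total read counts are not part of these values. Relative depth was estimated from the ratio between libraries at which the values of low genes pile up, since 1 fragment of a gene is worth an amount that falls with depth. This placed 7 libraries and could not place circulating ex-TRM replicate 1. Short genes gain large FPKM values from single fragments in shallow libraries, and a gene can be missed altogether, so a value of 0 was not taken as absence of expression. Where a group was listed at 0, the log2 difference depends on the pseudocount and is not read as a fold. A group of 1 library adds no spread. A pair of zeros adds none either but still counts as a pair of matching replicates, which lowers the SE and p of such genes.

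Before the data were examined, the tests, the lists of genes, the rule for naming genes and a set of alternatives were fixed. The plan assumed TPM. The files hold FPKM, so the planned test was run on log2(FPKM + 1), and log2 differences are on this scale, which understates the change of low genes. limma 3.58.1 in R 4.3.3 was fitted to group means of all 8 libraries with an intensity trend. It tested the 28389 genes with FPKM of at least 1 in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 7 comparisons were tissue against circulating and ex-TRM against ex-Tcirc, each averaged and within each level of the other factor, and their interaction. In all, 39 gene lists, 24 of programmes and 15 of cell type markers, were fixed. Lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01 and again with an estimated correlation.

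After the data had been examined, the comparisons were repeated over 7 libraries without circulating ex-TRM replicate 1, with a mean FPKM of at least 20, and over the 4 tissue libraries with the same minimum. The group of replication-dependent histone genes, and the tests on olfactory and vomeronasal receptor genes, were also chosen then. Named genes were the 10 highest and 10 lowest log2 differences among called genes with at least 5 FPKM in the higher group, no overlap between the libraries of the sides and no predicted gene symbol, members of the fixed lists that passed, and 16 genes fixed by name, of which 1 is not reported here. Where fewer than 5 genes per direction passed, the 5 with the smallest p that met the other criteria were named. Genes above 0 in both circulating ex-Tcirc libraries were named after their values had been seen, as were the examples given for lists and cell types.

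Each fit was tested on simulated data with 66 changed genes at each of log2 changes of 1, 2 and 4. For tissue against circulating, 0%, 4.5% and 34.8% of them were called over 8 libraries and 0%, 7.6% and 50% over 7 libraries, the latter with 5 false calls. For ex-TRM against ex-Tcirc in tissue, 0%, 0% and 15.2% were called over 8 libraries, and none over the 4 tissue libraries without the minimum of 20 FPKM, which was part of the reason for that minimum. Alternatives were a pseudocount of 0.1, no filter, genes above 0 in all libraries, median-of-ratios factors, TPM rescaled from FPKM, the replicate number as a block, library weights, the highest value per gene name, only the groups compared, other minimums, location or origin as the only term, and leaving out each library.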

Results

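RNA-seq profiles of mouse memory T helper cells were compared along the location from which the cells were recovered and the population from which they derived. The labels name 4 groups of 2 libraries each, tissue ex-TRM, tissue ex-Tcirc, circulating ex-TRM and circulating ex-Tcirc, where TRM stands for tissue-resident memory cells and Tcirc for circulating memory cells. The design text describes Th2 cells, helper cells that make type 2 cytokines, which were established as lung memory cells in recipient mice and sorted at day 49 of one experiment or day 71 of another. The labels of the RNA libraries do not say which experiment they come from, nor whether all 4 groups come from the same one. Differences between groups may therefore include differences between experiments. Whether libraries of a group came from separate animals is not stated either. The p-values thus measure only the spread between these libraries, which may be technical. A further 14 ATAC-seq samples are not analysed here.

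The 8 libraries differed widely in how many genes they detected. Of 55291 gene names per library, 37471 and 37894 were listed above 0 in tissue ex-TRM, 30488 and 32617 in tissue ex-Tcirc, 12785 and 7042 in circulating ex-Tcirc, and 917 and 29688 in circulating ex-TRM. From the steps between low FPKM values, tissue ex-TRM replicate 1 was the deepest library, and circulating ex-Tcirc replicates 1 and 2 had 8.6% and 4.02% of its depth. Circulating ex-TRM replicate 2 had 25.3%, close to the 24.1% of tissue ex-Tcirc replicate 1. Circulating ex-TRM replicate 1 could not be placed and listed only 1 of 12 housekeeping genes above 0. Genes that every cell uses were thus among the zeros, and a gene without signal is described here as listed at 0. FPKM values are given per library in the order replicate 1, replicate 2.

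**Figure D1:**
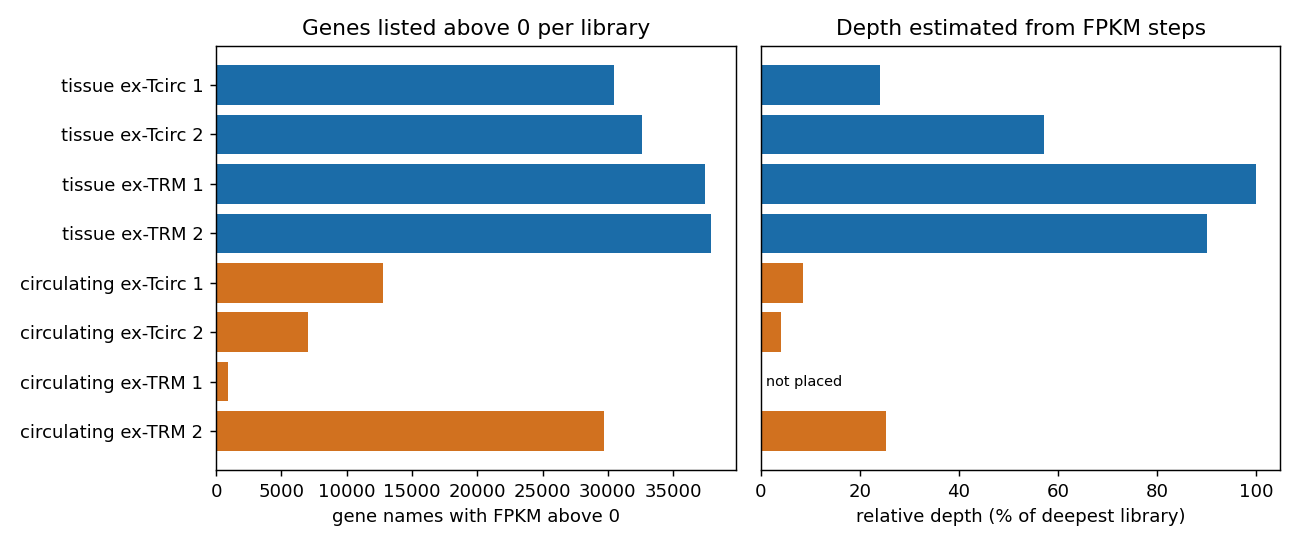
Left, number of gene names with FPKM above 0 in each of the 8 libraries (blue bars, tissue; orange bars, circulating). Right, depth relative to the deepest library, in percent, estimated from the steps between low FPKM values; circulating ex-TRM replicate 1, with 917 genes above 0, could not be placed.

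The first comparison asked which genes differ between cells in tissue and cells in circulation, averaged over both origins. Klf2, a transcription factor that sustains expression of tissue egress receptors, was at 26.1 and 20.9 FPKM in tissue ex-Tcirc and at 31 and 28.4 in tissue ex-TRM, against 183 and 159 in circulating ex-Tcirc and 174 in circulating ex-TRM replicate 2. Tcf7, a transcription factor of naive and central memory T cells, was at 35 to 57 FPKM in the 4 tissue libraries and at 145, 106 and 165 in the same 3 circulating libraries. The sphingosine phosphate receptor S1pr1, which T cells use to leave tissue, was at 2.99 to 5.34 FPKM in tissue and at 46.4 in circulating ex-Tcirc replicate 1 and 59.5 in circulating ex-TRM replicate 2, but was listed at 0 in circulating ex-Tcirc replicate 2. In the opposite direction, Il2ra, the interleukin 2 receptor alpha chain, was at 69.3 to 89.3 FPKM in tissue and at 15.6, 15.4 and 50.5 in these circulating libraries. Ecm1, a gene of the Th2 list, was at 54.6 to 64.9 FPKM in tissue and at 16.8, 21.3 and 25.1 in circulation.

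No gene passed the planned test of all 8 libraries. limma called 0 of 28389 genes, with 8115 at an unadjusted p under 0.05 and a smallest adjusted p of 0.103, while the median log2 difference over all genes was 0.99. Genes are listed by smallest p, here and for the other comparisons over 8 libraries, only among those that met the criteria for naming. The first 5 on the tissue side, Traj58, Eya2, Wdr45, Mir6920 and Hmces, were at 10.3 to 30.5 FPKM in the tissue libraries and listed at 0 in all 4 circulating libraries. On the circulating side, Pde2a, a cyclic nucleotide phosphodiesterase, was at 2.02 to 5.93 FPKM in tissue and at 21.1, 34.2, 18.1 and 13.7 in circulation. Snord116l13, Snord116l1, Snord116l6 and Pgap1 owed their place to 85.5 to 580 FPKM in circulating ex-TRM replicate 1. None of these 10 genes passed. Without that library, and over 2656 genes with a mean FPKM of at least 20, limma called 195 genes, 174 higher in tissue and 21 higher in circulation, with a median log2 difference over all genes of 0.43. These 7 libraries and this minimum were chosen after the data had been examined.

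Klf2 had a log2 difference of -2.67 ± 0.22 (SE; limma adjusted p = 0.0239) over the 7 libraries, and Tcf7 of -1.59 ± 0.23 (limma adjusted p = 0.0361). Both belong to the recirculation list, of which 9 members were tested. The cytoskeletal genes Flna, Ezr and Myo1f also passed on the circulating side, with log2 differences of -1.32, -1.24 and -1.75. On the tissue side, Il2ra passed with 1.46 ± 0.23 (limma adjusted p = 0.0399), Ecm1 with 1.41 ± 0.24 (limma adjusted p = 0.0464) and Rbpj, the DNA-binding partner of Notch, with 1.54 ± 0.25 (limma adjusted p = 0.0454). Restricted to the 1558 genes above 0 in all 7 libraries, Klf2 alone was called (limma adjusted p = 0.0471), and with location as the only term again Klf2 alone (limma adjusted p = 0.037). The 195 calls fell to 0 when any 1 of the 4 tissue libraries was left out and rose to 1860 and 1172 without circulating ex-Tcirc replicate 1 and 2.

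Genes of the Th2 programme lay higher in tissue, mostly through zeros in circulating ex-Tcirc, as did Cxcr6 and Ccr8, the 2 called of 16 tested members of the residency list, which did not pass as a list over the 7 libraries (camera adjusted p = 0.195). Ccr8, a chemokine receptor of Th2 cells, was at 43.7 and 66.6 FPKM in tissue ex-Tcirc, 83.6 and 68.6 in tissue ex-TRM and 4.59 in circulating ex-TRM replicate 2. Cxcr6, a chemokine receptor of resident T cells, was at 60.7, 72.7, 88.8 and 70.4 FPKM in tissue and 41 in that circulating library. Il1rl1, an alarmin receptor chain of Th2 cells, was at 82.7, 110, 112 and 64 FPKM in tissue and 34.5 in it. All of these were listed at 0 in both circulating ex-Tcirc libraries and passed over the 7 libraries (limma adjusted p = 0.0239 for each). For these genes the spread came from the tissue libraries alone, since a pair of zeros and a single circulating ex-TRM library add none. The pair of zeros still counted as matching replicates, which lowers their SE and p. The cytokine genes Il5, at 9.22 to 14.3 FPKM in tissue, and Il13, at 4.64 to 7.37, were listed at 0 in all 4 circulating libraries. Il4 was at 0 and 3.85 FPKM in tissue ex-Tcirc, 7.85 and 11.9 in tissue ex-TRM and 0 in circulation.

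Of the 10 members of the Th2 list tested over the 7 libraries, 6 passed over all genes and 6 when adjusted over the list alone, namely Ccr8, Il1rl1, Tnfsf11, Calca, Csf2 and Ecm1. Of these, Csf2 was at 21.2 to 44.4 FPKM in tissue and at 48.2 in circulating ex-TRM replicate 2, so that its difference came from circulating ex-Tcirc. Of 174 calls higher in tissue, 156 were listed at 0 in both circulating ex-Tcirc libraries, as were 188 of the 2656 genes tested, whereas all 21 calls higher in circulation were above 0 in both. A gene at 0 in both of these libraries could hardly be called higher in circulation, so this contrast between the sides was largely fixed in advance. Among the tissue-side calls with the largest log2 differences were the small nucleolar RNAs Snord14d, Snord57, Snord49b, Snord58b, Snord21, Snord60 and Snord66, at 62.8 to 1810 FPKM in tissue and 14.2 to 375 in circulating ex-TRM replicate 2. The same rule named the T cell receptor segments Trav5n-4 and Trav5d-4, near-identical copies whose reads may have been split between them, at 271 to 363 FPKM in tissue and 241 and 239 in that circulating library.

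**Figure D2:**
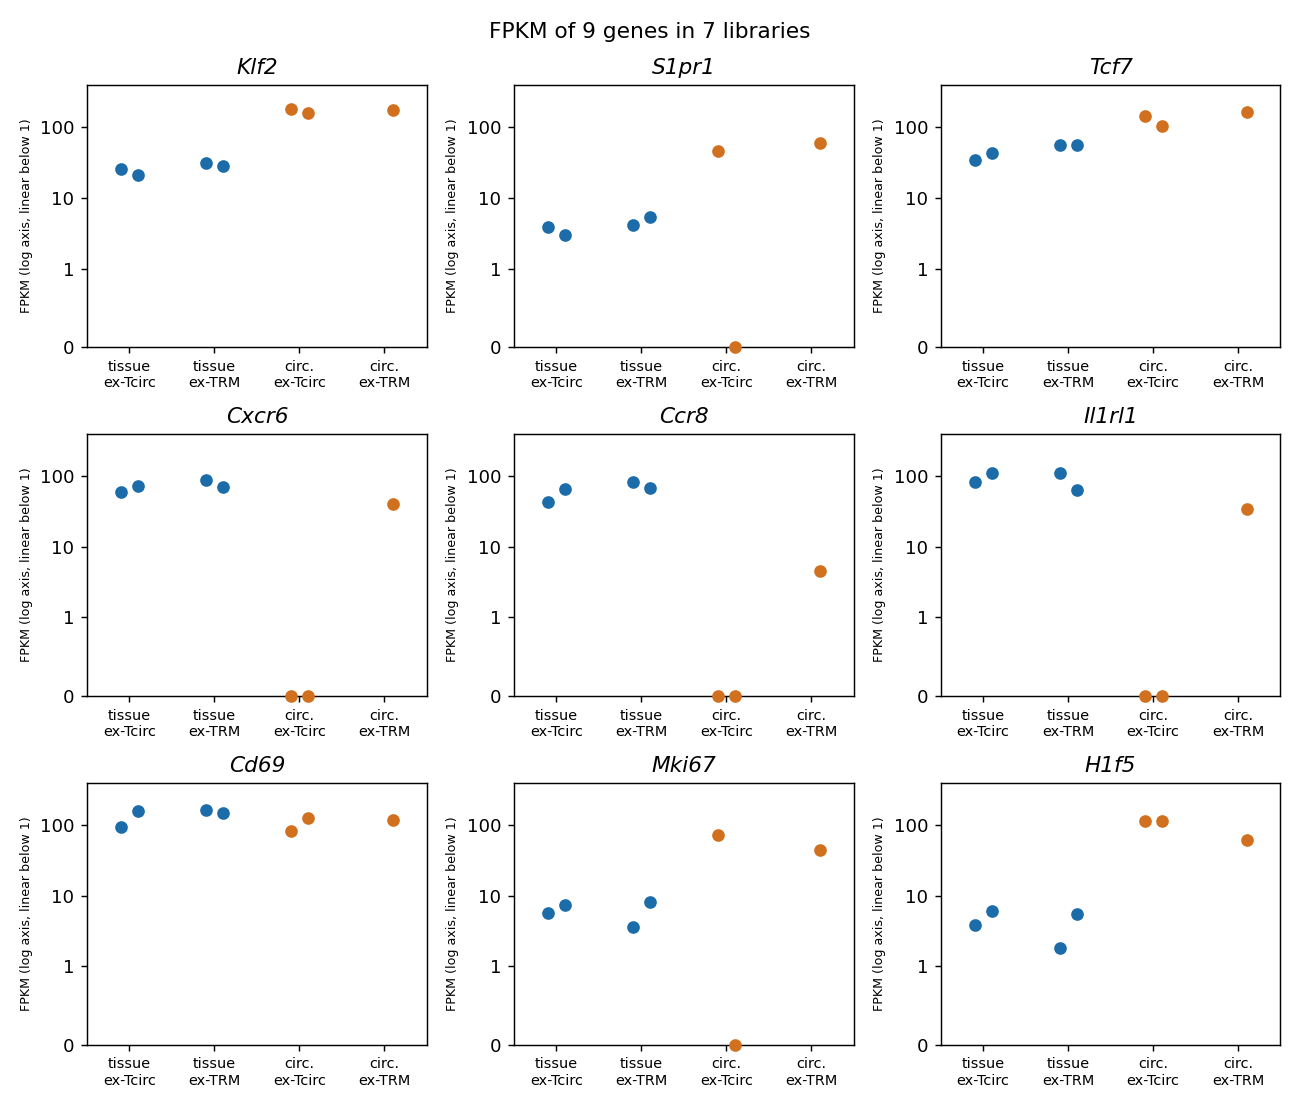
FPKM of 9 genes (log axis, linear below 1) in 7 libraries, 1 point per library (blue, tissue; orange, circulating), by group; circulating ex-TRM replicate 1 is not drawn. Klf2 lies at 20.9 to 31 FPKM in tissue and at 159 to 183 in circulation, while Ccr8, Cxcr6 and Il1rl1 are listed at 0 in both circulating ex-Tcirc libraries.

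Replication-dependent histone genes, a group singled out after the calls had been seen, were higher in circulation. Their median over 61 genes was 6.96 and 7 FPKM in tissue ex-Tcirc and 5.04 and 7.43 in tissue ex-TRM, against 132 and 18.7 in circulating ex-Tcirc and 58 in circulating ex-TRM replicate 2. H1f5, a linker histone, was at 1.82 to 6.14 FPKM in tissue and at 116, 116 and 61.9 in circulation (log2 difference -4.09 ± 0.46, SE; limma adjusted p = 0.0262). H3c8 was at 3.24 to 5.32 FPKM in tissue and at 132, 238 and 34.7 in circulation (-3.86 ± 0.39, SE; limma adjusted p = 0.0253). Of 44 histone genes tested over the 7 libraries, all 44 were lower in tissue and 10 passed over all genes, the other 8 being H2bc3, H3c15, H2ac14, H1f1, H2ac20, H1f2, H4c3 and H4c4. Because the group was picked from these calls, its counts describe it and do not test it. Histone genes are a family of near-identical copies, and reads may have been split among them. The proliferation marker Mki67 was at 3.65 to 8.04 FPKM in tissue, 71.3 and 0 in circulating ex-Tcirc and 45 in circulating ex-TRM replicate 2, and Top2a was at 3.34 to 7.4 FPKM in tissue and 46.5, 21.1 and 21.2 in circulation. Neither passed a test between tissue and circulation.

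Cd69, the gene in the title of the study, whose product retains T cells in tissue, showed no such separation. Its FPKM was 92.8 and 156 in tissue ex-Tcirc, 162 and 150 in tissue ex-TRM, 81.2 and 125 in circulating ex-Tcirc and 120 in circulating ex-TRM replicate 2 (log2 difference 0.31 ± 0.31 over 7 libraries, SE; limma adjusted p = 0.704). Gata3, the lineage factor of Th2 cells, was at 194 to 274 FPKM in tissue and at 49.4, 231 and 186 in circulation (0.70 ± 0.63, SE; limma adjusted p = 0.681). Cd4 was at 65.9 to 109 FPKM in tissue and at 78.3, 138 and 139 in circulation (limma adjusted p = 0.573). The integrin gene Itgae stayed at or below 4.57 FPKM in every library. The chemokine receptor gene Ccr7 reached 17.8 FPKM in circulating ex-TRM replicate 2 and at most 2.48 in tissue, and was listed at 0 in circulating ex-Tcirc. Areg, Tbx21 and Foxp3 were at 19.5 to 34.6, 7.79 to 26.6 and 2.65 to 8.3 FPKM in tissue and at 27.8, 20.6 and 5.52 in circulating ex-TRM replicate 2, and were listed at 0 in both circulating ex-Tcirc libraries.

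Of 35 gene lists tested with camera at a preset correlation over the 8 libraries, 7 passed for location. The Th2 list lay above the other genes (27 of 27 tested members positive, median log2 difference 2.85; camera adjusted p = 1.31e-06, but adjusted p = 0.995 with an estimated correlation), with 20 members passing when adjusted over the list alone and 0 over all genes. The residency list did so too (30 of 30 positive, median 2.24; camera adjusted p = 0.0135), as did nuclear oxidative phosphorylation (47 of 47 positive, median 2.16; camera adjusted p = 0.0336), again both at adjusted p = 0.995 with an estimated correlation. Positive members do not set these lists apart, since 32 of 32 immediate early and 17 of 17 T cell identity genes were positive without passing (camera adjusted p = 0.673 and 0.951). Above the median over all genes lay 23 of 27 Th2, 25 of 30 residency and 42 of 47 oxidative phosphorylation genes. All of the immediate early and T cell identity genes did as well. The cell cycle list (17 of 31 positive, median 0.26; camera adjusted p = 0.0021), the recirculation list (12 of 19 positive, median 0.66; camera adjusted p = 0.00253), and fibroblast markers (5 of 9 positive, median 0.03; camera adjusted p = 0.0021) lay below the other genes, with medians above 0 but under the median of 0.99 over all genes. Mitochondrially encoded genes also passed downward (camera adjusted p = 0.0336), although their median of 1.52 lay above that of all genes, so this call has no clear direction. These 4 lists too had an adjusted p = 0.995 with an estimated correlation. Over the 7 libraries 3 of 19 lists passed, Th2 upward (camera adjusted p = 0.00108) and recirculation (camera adjusted p = 0.0422) and mitochondrially encoded genes (camera adjusted p = 0.00381) downward, and the smallest adjusted p was 0.598 with an estimated correlation. Without circulating ex-Tcirc replicate 1 none of these 3 lists passed.

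Genes of other cell types varied between libraries, and Lyz2 was high in both circulating ex-Tcirc libraries. In circulating ex-Tcirc replicate 1, the myeloid gene Lyz2 was at 646 FPKM, the alveolar epithelial gene Sftpc at 421, and the antigen presentation genes Cd74 and H2-Ab1 at 265 and 113. In replicate 2 of that group they were at 255, 0, 7.62 and 0 FPKM. In tissue ex-Tcirc replicate 1, the immunoglobulin genes Igkc and Ighm were at 281 and 111 FPKM and Lyz2 at 114, against 41.4, 21 and 29.7 in tissue ex-Tcirc replicate 2. In tissue ex-TRM the same genes were at 12.1 and 32.5, 7.11 and 16.6, and 49.7 and 77.5 FPKM, and in circulating ex-TRM replicate 2 at 24.9, 8.84 and 50.6.

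The location comparison was repeated within each origin. For ex-Tcirc cells, limma called 0 of 28389 genes over the 8 libraries, with 5947 at an unadjusted p under 0.05. The genes with the smallest p were Snord45c, Trdd2, Neil3, Snord14d and C87436 on the tissue side, and Rnu11, Rps12l1, H3c14, Hpgd and Olfr165 on the circulating side. Of these, Hpgd, which inactivates prostaglandins, was at 0 and 0.174 FPKM in tissue ex-Tcirc and at 5.38 and 23.9 in circulating ex-Tcirc. Over the 7 libraries 242 genes were called, 222 higher in tissue, of which 183 were listed at 0 in both circulating ex-Tcirc libraries. The 20 lower in tissue included Klf2 (log2 difference -2.82 ± 0.28, SE; limma adjusted p = 0.00742), H4c4 and the pseudogene Atp6v0c-ps2. Rps15, a ribosomal protein gene, and Il1rl1 were among the 10 largest on the tissue side. With genes above 0 in all 7 libraries, 13 genes were called.

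For ex-TRM cells, limma called 0 of 28389 genes over the 8 libraries, with 2760 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0595. Polr2j, Psmg4, Trav17, Ptprcap and Pfdn4 had the smallest p, at 5.22 to 50.4 FPKM in tissue ex-TRM and listed at 0 in all other libraries, tissue ex-Tcirc included. Magea4, Snord116l9, Exoc3l2, H2bc9 and Fam57b stood on the circulating side through 55.4 to 743 FPKM in circulating ex-TRM replicate 1. Over the 7 libraries, where circulating ex-TRM is a single library, limma called 0 of 2656 genes, with 87 at an unadjusted p under 0.05. In camera tests over the 8 libraries, 5 of 35 lists passed for ex-Tcirc and 10 for ex-TRM, and the smallest adjusted p was 0.988 and 0.925 with an estimated correlation.

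The next comparison asked what differs between cells of ex-TRM and ex-Tcirc origin, averaged over both locations. Eomes, a T-box transcription factor of cytotoxic and memory T cells, was at 13.7, 13.4, 15.6 and 37.3 FPKM in the ex-Tcirc libraries and at 2.51, 5.29, 0 and 6.93 in the ex-TRM libraries, and did not pass (limma adjusted p = 1). limma called 0 of 28389 genes over the 8 libraries, with 1046 at an unadjusted p under 0.05. The other genes that met the criteria for naming were Trim3, Pvr, Ppp1cc, Smarca5 and Clasp1 on the ex-TRM side and Olfr352, Palm3, Parp16 and Mir6516 on the ex-Tcirc side, most of them with an unadjusted p over 0.05 in limma. In the fit of 7 libraries 132 genes were called, all higher in ex-TRM and all listed at 0 in both circulating ex-Tcirc libraries. They included Lrch4, Socs2, Cd40lg, Lyst, Traj9, Ptpn6, Rbck1, Cdc42, Arpc5 and Nfkbib. Their spread, too, came from the tissue libraries alone, with the pair of zeros counted as matching replicates, which lowers their SE and p. Cd40lg, which T helper cells use to activate B cells, was at 61.6 and 91.7 FPKM in tissue ex-Tcirc, 125 and 115 in tissue ex-TRM and 93.4 in circulating ex-TRM replicate 2. No gene was called among those above 0 in all 7 libraries, where 71 had an unadjusted p under 0.05 in limma, nor when any 1 tissue library was left out, while 1663 and 472 were called without circulating ex-Tcirc replicate 1 and 2.

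Within circulation, limma called 0 of 28389 genes between origins over the 8 libraries, with 341 at an unadjusted p under 0.05. Eftud2, Trim3, Esrra, Cpa6 and Far2 had the smallest p on the ex-TRM side, and Rnu11, Rps12l1, H3c14, Olfr165 and Etfbl on the ex-Tcirc side. Over the 7 libraries 176 genes were called, 175 higher in the single ex-TRM library, and 166 of these were listed at 0 in both ex-Tcirc libraries. Ribosomal protein genes were among the largest, with Rps15 at 255, Rpl37a at 134, Rpl26 at 109 and Rpl27 at 104 FPKM in circulating ex-TRM replicate 2 and all 4 listed at 0 in circulating ex-Tcirc. In camera tests over the 8 libraries, 6 of 35 lists passed both for the averaged origins and within circulation, all downward, and the smallest adjusted p was 0.982 and 0.994 with an estimated correlation. The tests over 7 libraries left out the library with 917 genes above 0 and raised the minimum FPKM, so library and minimum changed together. There 2 of 19 lists passed for each, Th2 upward (camera adjusted p = 0.0033 and 0.0063) and mitochondrially encoded genes still downward (camera adjusted p = 0.0033 and 0.0123). The smallest adjusted p was 0.979 and 0.841 with an estimated correlation. Immediate early genes also stayed downward, without passing (camera adjusted p = 0.944 and 0.196). Ribosomal protein and T cell identity genes turned upward without passing. Monocyte and fibroblast markers had too few members to be tested.

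Within tissue, cells of ex-TRM origin had more Nr4a2, an orphan nuclear receptor induced by T cell receptor signals. The 4 tissue libraries listed 30488 to 37894 genes above 0, but were not alike. Relative depth was 100% and 90.1% in tissue ex-TRM and 24.1% and 57.2% in tissue ex-Tcirc. Protein-coding names held 12.3% and 14% of the FPKM sum in tissue ex-TRM and 10.2% and 10.5% in tissue ex-Tcirc. Both measures thus separated the origins in tissue and cannot be told apart from origin. Log2 values of tissue ex-Tcirc replicate 1 correlated at 0.77 (Pearson) with replicate 2 and with both tissue ex-TRM libraries. Replicate 2 correlated with those at 0.95 and 0.94, so 1 ex-Tcirc library stood apart in this contrast. Nr4a2 was at 141 and 104 FPKM in tissue ex-TRM and at 16.8 and 17.2 in tissue ex-Tcirc (log2 difference 2.76 ± 0.21, SE; limma adjusted p = 0.0968), and Lrch4 was at 64.6 and 55.2 against 6.37 and 9.26 FPKM (2.80 ± 0.25, SE; limma adjusted p = 0.101). The interleukin 4 receptor gene Il4ra was at 43.4 and 39.9 against 15.6 and 18.4 FPKM, Wac at 70.2 and 52.1 against 15.6 and 22.1, and Cd5, an inhibitor of T cell receptor signalling, at 35.3 and 47.9 against 8.85 and 13.3 (limma adjusted p = 0.488 for each). Micos10, mt-Te, Rpl31-ps8, Snora65 and H2-Q10 led the ex-Tcirc side, with log2 differences of -1.71, -0.97, -0.76, -1.20 and -0.67 (limma adjusted p = 0.488 for each). None of these passed the test of the 2818 genes with a mean FPKM of at least 20 in the 4 tissue libraries, a set chosen after the data had been examined. limma called 0 of them, with 215 at an unadjusted p under 0.05. In simulations of this fit, 28.8%, 86.4% and 87.9% of genes changed by 1, 2 and 4 on the log2 scale were called, with 3 false calls. The simulations planted 66 changed genes at each size, with random spread but no zeros and no differences in depth. They therefore do not give the power behind the 0 calls, and Nr4a2, at 2.76, did not pass. The planned fit of 8 libraries also called 0 of 28389 genes, with 1032 at an unadjusted p under 0.05. Its smallest p belonged to Polr2j, Psmg4, Trav17, Ptprcap and Pfdn4 on the ex-TRM side, and to Mir26b, Trdd2, Ighj4, Mir147 and Pf4 on the ex-Tcirc side.

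Genes of residency and of recent activation had positive differences toward ex-TRM in tissue, in tests that none of the lists passed with an estimated correlation. Depth and the share of protein-coding names also separate these libraries by origin, so their part in these differences cannot be told apart. All 17 tested members of the residency list had positive differences (median log2 difference 0.64; camera adjusted p = 0.00022, but adjusted p = 0.801 with an estimated correlation), among them Rgs1 at 114 and 122 against 56.7 and 70.8 FPKM and Icos at 38.3 and 38.5 against 19.1 and 25.7. Of 25 immediate early and receptor-induced genes, 24 were positive (median 0.43; camera adjusted p = 0.000544, and adjusted p = 0.801 with an estimated correlation), with Nr4a1 at 254 and 224 against 130 and 165 FPKM, Nr4a3 at 218 and 169 against 88.5 and 112, and Egr1 as the exception at 55.3 and 77.4 against 65 and 88.1. All 8 tested members of the TGF-beta response list were positive (median 0.68; camera adjusted p = 0.00677, and adjusted p = 0.801 with an estimated correlation), including Tgfbr2 at 25.8 and 32.4 against 16.4 and 18.7 FPKM and Tgif1 at 37.9 and 36.2 against 21.5 and 24.4. The median over all genes was 0.20, and Nr4a1, Nr4a2 and Cd69 belong to both of the first lists. Over all genes 0 members of these lists passed, and adjusted over the list alone 1, 1 and 2 did. These were 3 of 20 lists. T cell identity genes went the same way without passing (16 of 17 positive, median 0.29; camera adjusted p = 0.0694), whereas fibroblast markers went toward ex-Tcirc over 8 libraries (0 of 9 positive, median -0.59; camera adjusted p = 0.191), and tissue ex-Tcirc replicate 1 had the highest Lyz2, Igkc and Apoe of the tissue libraries. In the planned fit of 8 libraries none of 35 lists passed. Cd69, Cxcr6 and Klf2 had log2 differences of 0.37 ± 0.30, 0.25 ± 0.22 and 0.33 ± 0.20 (SE) between origins in tissue, and Gata3, Il1rl1 and Areg of 0.12 ± 0.26, -0.17 ± 0.33 and -0.11 ± 0.31, none past the threshold.

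**Figure D3:**
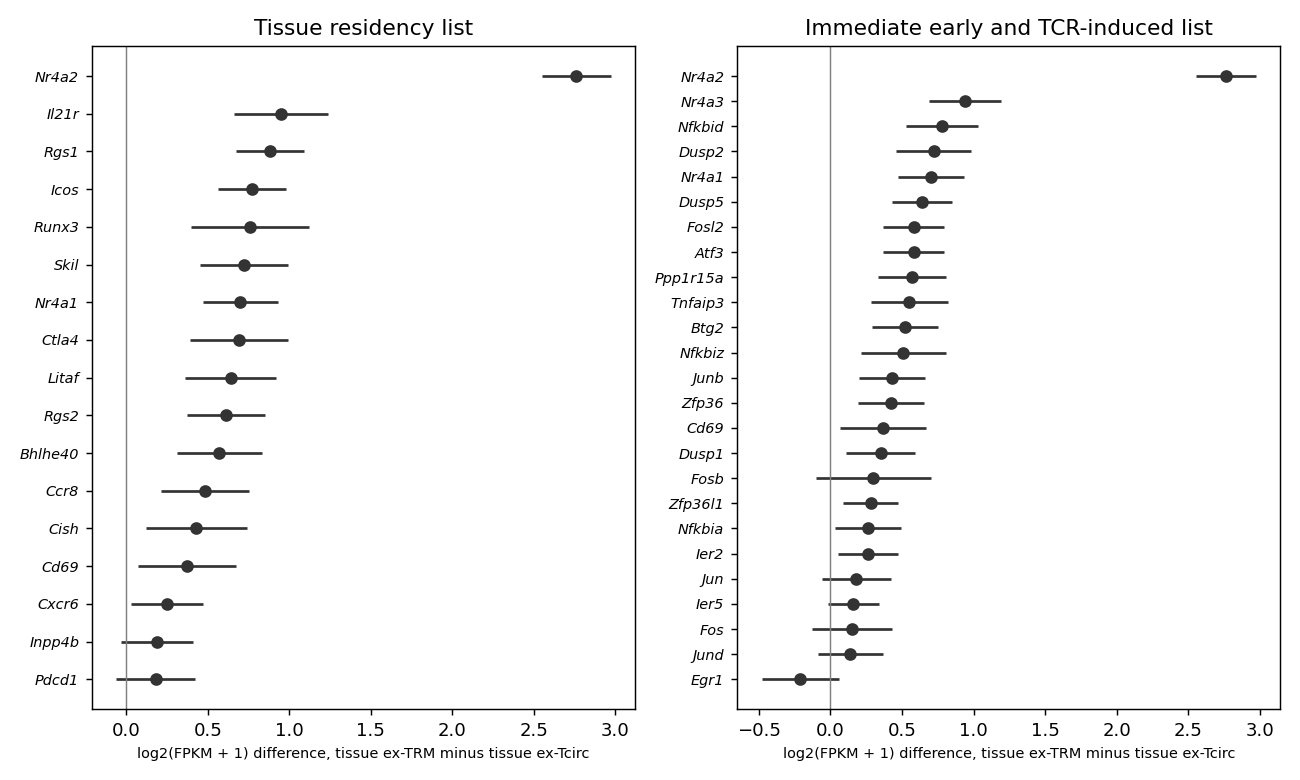
Difference in log2(FPKM + 1) between tissue ex-TRM and tissue ex-Tcirc (2 libraries each) for the tested members of the residency list (left, 17 genes) and of the immediate early list (right, 25 genes); points are limma estimates and bars standard errors, and positive values are higher in ex-TRM. Nr4a2 lies at 2.76 and Egr1 below 0.

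The last comparison asked whether the difference between tissue and circulation depends on origin. limma called 0 of 28389 genes over the 8 libraries, with 754 at an unadjusted p under 0.05. Over the 7 libraries 4 genes were called, Rps15, Snord58b, Trav5n-4 and Trav5d-4. Each was listed at 0 in both circulating ex-Tcirc libraries and well above 0 in the other 5 libraries, with Rps15 at 252 and 209 FPKM in tissue ex-Tcirc, 185 and 179 in tissue ex-TRM and 255 in circulating ex-TRM replicate 2. In camera tests 7 of 35 lists passed over the 8 libraries, all upward, with immediate early genes first (27 of 32 positive, median 3.57; camera adjusted p = 1.37e-05), and the smallest adjusted p was 0.994 with an estimated correlation. Circulating ex-TRM replicate 1 listed 1 of the 32 immediate early genes above 0, against 27, 21 and 32 in the other circulating libraries. Their median difference between origins in circulation was -3.14 over 8 libraries, against 0.21 over all genes. Without that library, and for the 25 members with a mean FPKM of at least 20, it was 0.23, against 1.06 over all genes. The list median thus still lay below that of all genes, and library and minimum changed together.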

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

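The tests of the difference between origins over 7 libraries and both tests on the one-sided calls were chosen after the data had been examined. Over 7 libraries, the difference between tissue and circulation differed between origins for 4 genes by limma's interaction term. The coefficient, the tissue minus circulating difference in ex-TRM less that in ex-Tcirc, was -8.33 ± 0.44 for Rps15 (SE; limma adjusted p = 0.0323), -6.88 ± 0.45 for Snord58b (limma adjusted p = 0.0456), -7.73 ± 0.43 for Trav5d-4 and -7.76 ± 0.43 for Trav5n-4 (limma adjusted p = 0.0323 for both). All 4 are listed at 0 in both circulating ex-Tcirc libraries, so these coefficients depend on the pseudocount, and Trav5n-4 and Trav5d-4 share most of their sequence. Their SE reflects spread between tissue libraries only, and the pair of zeros, counted as matching replicates, lowers it. Over genes above 0 in all 7 libraries the interaction called 0 genes in limma, with 71 at an unadjusted p under 0.05.

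The same zeros carried most calls made over 7 libraries. Low depth in the 2 circulating ex-Tcirc libraries would also strike genes every cell uses. Of the 63 tested ribosomal protein and oxidative phosphorylation genes, 6 were at 0 in both. This was 9.52%, which lies between the bounds of 5 and 10 percent set for the test. Of all 2656 genes tested, 188 were at 0 in both, or 7.08%, so genes every cell uses were not spared. A difference between cells in tissue and in circulation would also show in circulating ex-TRM replicate 2, which lay below every tissue library for 77 of the 174 tissue-higher calls, or 44.3%. Genes picked without regard to that library would give 20%, but these calls were picked partly on it. The share is under the 60 percent below which the explanation was to be ruled out. That verdict was withdrawn after the value had been seen, because it rests on a single library that also took part in selecting these calls, and a difference limited to ex-Tcirc cells would not show in it, so the explanations cannot be told apart. Low depth may account for Rps15, and a lower level in circulation may account for Ccr8, at 4.59 FPKM in the deeper circulating library, but neither was tested gene by gene.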

How the results depend on the processing

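All fits over 7, 6 or 4 libraries and the TPM scale were added after the data had been examined; the other alternatives over 8 libraries were planned. The cause of a change was not tested unless stated. For tissue against circulating, the count of 0 over 8 libraries became 1817 (1806 higher in tissue) with log2(FPKM + 0.1), 1145 (1135 higher) with median-of-ratios factors, 195 over 7 libraries, 1 over 7 libraries with genes above 0 in all, and 1172 over 6 libraries, also without circulating ex-Tcirc replicate 2; leaving out 1 library gave 0 to 12303, the highest without circulating ex-TRM replicate 2, then 3618 without circulating ex-TRM replicate 1, and 2815 and 3405 without tissue ex-Tcirc replicate 1 and 2. For ex-TRM against ex-Tcirc it became 132 over 7 and 472 over 6 libraries, and 0 to 3319 leaving out 1 (3319 and 1639 without circulating ex-TRM replicate 1 and 2, 1115 without tissue ex-Tcirc replicate 2). For location in ex-Tcirc it became 3037 with library weights, 5389 with only the 2 groups, 242 over 7 libraries, 13 with genes above 0 in all 7, 1190 over 6, and 0 to 6340 leaving out 1 (5984 and 6340 without circulating ex-TRM replicate 1 and 2, 546 without tissue ex-Tcirc replicate 2, 2 without circulating ex-Tcirc replicate 2). For location in ex-TRM it became 556 with log2(FPKM + 0.1), 559 with median-of-ratios factors, 1767 with only the 2 groups, 60 over 6 libraries, and 0 to 8705 leaving out 1 (8705 without circulating ex-TRM replicate 2, 2647 and 2232 without tissue ex-Tcirc replicate 1 and 2). For origin in tissue it became 581 with log2(FPKM + 0.1), 571 with median-of-ratios factors, and 0 to 1520 leaving out 1 (605 and 1520 without tissue ex-Tcirc replicate 1 and 2). For origin in circulation it became 176 over 7 and 563 over 6 libraries, and 0 to 4400 leaving out 1 (4400 and 2181 without circulating ex-TRM replicate 1 and 2, 1 without circulating ex-Tcirc replicate 2 or tissue ex-TRM replicate 1). For the interaction it became 4 over 7 and 440 over 6, and 0 to 2099 leaving out 1 (2099 and 1829 without circulating ex-TRM replicate 1 and 2, 1120 without tissue ex-Tcirc replicate 2). Where a group was left with 1 library, that library was assumed to vary like the others. Without a filter, with the highest value per gene name, with genes above 0 in all 8 libraries and with TPM all 7 counts stayed at 0 in limma.

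Replicate numbers are shared between groups without a label that pairs them, and deviations of same-numbered libraries correlated at -0.26 to 0.18. With the replicate block all 7 counts stayed at 0 over 8 libraries (7004 unadjusted for location, against 8115), the 195 and 132 calls over 7 libraries became 0 and 0 (369 and 211 at an unadjusted p under 0.05 in limma), and the 0 calls over 4 tissue libraries became 3. Over 7 libraries the 195 location calls became 24 at a mean FPKM of at least 50, 1 above 0 in all 7, 113 with TPM, 56 with median-of-ratios factors, 1 with location as the only term and 0 over 8 libraries, and 0 to 1860 leaving out 1 (0 without any 1 tissue library, 1860 and 1172 without circulating ex-Tcirc replicate 1 and 2). The 132 origin calls became 3 (Rps15, Trav5d-4, Trav5n-4), 0, 2 (Trav5d-4, Trav5n-4), 0, 0 and 0 in the same order, and 0 to 1663 leaving out 1 (0 without any 1 tissue library, 1663 and 472 without circulating ex-Tcirc replicate 1 and 2). Over 4 tissue libraries the 0 calls became 3 with TPM (Nr4a2, Lrch4, Gm17300), the same 3 genes with the block, 5 with median-of-ratios factors (Nr4a2, Lrch4, Rps23, Rps18-ps4, Snora73b), and 0 to 429 leaving out 1, with 429 without tissue ex-Tcirc replicate 2 and 3 and 1 without tissue ex-TRM replicate 1 and 2. The median over all genes for location was 0.99 with FPKM, 0.74 with TPM and 1.02 with median-of-ratios factors over 8 libraries, and 0.43, 0.22 and 0.62 over 7.

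The count of lists that passed for location, 7 of 35, became 12 of 35 with library weights, 3 of 19 over 7 libraries, 0 of 11 with genes above 0 in all 7, and 4 to 11 leaving out 1 library (4 without tissue ex-Tcirc replicate 2, 11 without circulating ex-TRM replicate 2); no list had enough members above 0 in all 8 libraries. Without circulating ex-Tcirc replicate 1, 5 lists passed upward and 0 downward. Leaving out 1 library gave camera adjusted p up to 0.0015 for Th2, 0.518 for residency (lost without tissue ex-Tcirc replicate 1 or 2 or circulating ex-TRM replicate 1), 0.863 for recirculation and 0.25 for cell cycle (both lost without circulating ex-Tcirc replicate 1 or circulating ex-TRM replicate 2), and 0.283 for fibroblast markers (lost without circulating ex-Tcirc replicate 1 or tissue ex-Tcirc replicate 2). Of the lists that passed over 7 libraries, Th2 reached 0.354, recirculation 0.67 and mitochondrially encoded genes 0.0573, each without circulating ex-Tcirc replicate 1, and recirculation was also lost without tissue ex-Tcirc replicate 2. Oxidative phosphorylation turned downward over 7 libraries (camera adjusted p = 0.89), with genes above 0 in all 7 (0.496) and over 6 (0.354), and ranged from 0.00159 to 0.7 leaving out 1; mitochondrially encoded genes ranged from 5.28e-07 to 0.163, turning upward at 0.163 without circulating ex-TRM replicate 2. With circulating ex-TRM replicate 1 in the fit, which lists them at 0, the log2 differences of Cd4, Tcf7, Flna, Ezr, Rpl10a-ps1 and Rpl28-ps1 turned toward tissue, at 1.35, 0.26, 0.59, 0.65, 0.53 and 0.52. Klf2 kept its direction in every fit, from -2.86 with TPM to -0.80 over 8 libraries (limma adjusted p 0.000456 to 0.76), and lost its call over 8 libraries, with the block and without any 1 tissue library. In tissue, Il1rl1 turned to 0.02 and Areg to 0.07 with median-of-ratios factors, and Areg to 0.01 with TPM; leaving out 1 library gave 0 to 0.74 for Cd69, -0.07 to 0.31 for Gata3, -0.57 to 0.23 for Il1rl1 and -0.51 to 0.29 for Areg. The residency, immediate early and TGF-beta lists in tissue passed at the preset correlation under the alternatives of the 4-library fit in which they could be tested, but none did with an estimated correlation (adjusted p = 0.801) or over 8 libraries. Depth limits what the circulating groups can show: 6143 genes reached 1 FPKM in circulating ex-Tcirc replicate 2, against 25123 in tissue ex-TRM replicate 2.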

Other observations

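The separation of libraries in tissue, the tests on depth and on the histone genes as a group, and the splits of 8 libraries, were chosen after the results had been seen, and the test of depth on histone genes was then narrowed to single groups of libraries. The list genes were also read library by library in tissue, in the same 4 libraries as the list tests and so without independent evidence. Both tissue ex-TRM libraries lay above both tissue ex-Tcirc libraries for 21 of 30 residency genes, 23 of 32 immediate early genes, 12 of 17 TGF-beta response genes and 11 of 17 T cell identity genes, and for 9 of 28 Th2 genes. The reverse held for 3, 0, 0, 1 and 3 genes of these lists. Chance gives 16.7% in each direction, but of the 2818 genes with a mean of at least 20 FPKM in tissue 43.2% separated toward ex-TRM and 12% toward ex-Tcirc, and of all 29072 genes read this way 21.9% and 11.1%, so a large part of these counts is shared with other genes. Genes of a list are not independent. Tissue ex-Tcirc replicates 1 and 2 had 24.1% and 57.2% of the depth of the deepest library, against 100% and 90.1% in tissue ex-TRM. Among 8 tested costimulatory and inhibitory receptors, all 8 had positive differences toward ex-TRM in tissue (median log2 difference 0.61; camera adjusted p = 0.0694), with Ctla4 at 34.2 and 37.9 against 16.4 and 29.3 FPKM.

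Histone genes were above every tissue library for 60, 41 and 59 of 61 genes in circulating ex-Tcirc replicates 1 and 2 and circulating ex-TRM replicate 2. A hypothesis is that more of the circulating cells were cycling. Whether such cells were the sorted T cells was not tested, and circulating ex-Tcirc replicate 1 also held genes of other cell types. The cell cycle list was higher in circulating ex-TRM replicate 2 than in tissue by a median of 1.22 on the log2 scale (SD over 27 genes 1.07, 26 of 27 higher). Over all genes with a mean FPKM of at least 20, the median of tissue minus that library was -0.17. Mcm5 was at 14.7 FPKM in that library against 5.72 to 7.88 in tissue. In circulating ex-Tcirc, 15 of 27 cell cycle genes lay above every tissue library in replicate 1, but 2 did in replicate 2, where 17 were listed at 0 and the median difference turned toward tissue under FPKM, TPM and median-of-ratios scaling alike. There it was 1.16, 0.84 and 1.21 toward tissue, against 1.69, 1.03 and 1.87 over all genes with a mean FPKM of at least 20. Genes in general thus shared this turn. Low depth is argued against for circulating ex-TRM replicate 2, whose histone median was 8.34 times that of the equally shallow tissue ex-Tcirc replicate 1, but for the circulating ex-Tcirc libraries 0 tissue libraries were shallow enough to judge it, so low depth may contribute there. Genomic DNA is argued against by olfactory and vomeronasal receptor genes, silent in T cells, whose mean FPKM was 0.505, 1.36 and 1.08 in the 3 circulating libraries, far below their histone medians of 132, 18.7 and 58. In tissue it was 1.99 in ex-Tcirc replicate 1, so that circulating ex-TRM replicate 2 had 0.543 times as much, but 0.547, 0.681 and 0.849 in the other 3 libraries, so some genomic DNA in 2 of the circulating libraries is not excluded.

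Tissue ex-Tcirc replicate 1 listed 26554 genes at FPKM of at least 1, more than the deeper tissue ex-Tcirc replicate 2 with 20065, but fewer above 0, at 30488 against 32617. Circulating ex-TRM replicate 2, of similar depth, also listed more genes at 1 FPKM, 23685. Tissue ex-TRM replicate 2, at 90.1% of the depth of the deepest library, listed 25123. Circulating ex-Tcirc replicates 1 and 2, at 8.6% and 4.02%, listed 10500 and 6143. This count thus did not simply follow depth, whether depth explains the excess was not tested, and the excess is not read as a finding of its own. Receptor genes that should be silent had a mean of 1.99 FPKM in tissue ex-Tcirc replicate 1, 2.35 times the highest of the other tissue libraries. Genomic DNA in the library was set to need more than 3 times, and RNA of other cell types to leave it within 1.5 times, so the value decides neither. For the receptor genes, genomic DNA and RNA of other cells cannot be told apart as possible explanations, and they do not exclude each other. Lyz2 at 114, Igkc at 281 and Apoe at 116 FPKM were also higher in this library than in the other 3 tissue libraries, and far above the receptor mean of 1.99. No biological explanation was tested.

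Splits of the libraries, with group as the only term, show how far chance can be excluded. For tissue against circulating over 8 libraries, 2 of the 35 splits called at least 385 genes, the count of the real split, which is 1 of these 2. The other split called 1179, so chance is not excluded. That split put tissue ex-Tcirc replicate 1 with both circulating ex-Tcirc libraries and circulating ex-TRM replicate 1. These are the 3 libraries with the lowest depth of the 7 that could be placed, at 24.1%, 8.6% and 4.02%, and the unplaced library with 917 genes above 0. The split does not simply follow detection. Tissue ex-Tcirc replicate 1 listed 30488 genes above 0, against 29688 in circulating ex-TRM replicate 2, which lay outside it at a depth of 25.3%. What these libraries share was not tested. For ex-TRM against ex-Tcirc over 8 libraries, the real split called 0 genes in limma, so that all 35 of 35 splits called as many by necessity, the highest other again 1179. Over 7 libraries, the real tissue split called 1 gene, Klf2, and 1 of 35 splits, the real one, called as many, the highest other calling 0. A difference of 1 call, in libraries chosen after the data had been examined, is too small to exclude chance. For origin over 7 libraries the real split also called 0 genes, 35 of 35 splits called as many and the highest other called 1. Neither origin count tests chance.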
